A study of Homo sapiens with 15 samples.

How the data were processed

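Messenger RNA was measured in HEK-293 cells that were untreated or transfected with a GEMIN5 expression plasmid by a lipid reagent, in cytoplasmic lysates and in polysome fractions (8 to 12 of 12, from 10 to 50% sucrose gradients), after the ribosomes had been held in place with cycloheximide, per the labels' protocols. Libraries were made with a stranded poly(A) kit, per the labels. Samples were assigned to the groups Input control (n = 4), Input GEMIN5 (n = 3), Polysome control (n = 4) and Polysome GEMIN5 (n = 4) by their titles. The labels call them independent biological samples but do not say how the cultures were separated, so p-values measure the spread between these samples.

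Gene counts were deposited by the authors as raw whole-number reads for 21519 Ensembl genes. Per the submitters' processing notes, STAR 2.7.10a and featureCounts (version not given in the sources used here) were used with GRCh38/hg38. The counting options and the use of strand are not given in the sources used here. The gene length in the deposited table equals the whole gene span for all 21519 genes, so it is open whether reads in introns were counted, and reads of overlapping or antisense genes and of near-identical copies are uncertain. Symbols and coordinates came from an annotation of the same build, which matched 21494 IDs. Splicing was deposited by the authors as percent spliced in (PSI), a percent per event and library for 721551 events, in the layout of a vast-tools table for hg38 per the file headers, with its version not given in the sources used here. The deposited quality column of the same table, of the unit other (a text field), holds the corrected numbers of inclusion and exclusion reads, which are not plain reads. For 2168048 values with at least 10 reads, 100% of PSI values lay within 0.5 points of the share of inclusion reads.

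Total counts were 11191417 to 18407933 per library. Genes were kept by edgeR's filterByExpr (12197), scaled by TMM, and tested in 1 fit over all 15 libraries with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The contrasts were GEMIN5 against control in Input and in polysomes, the difference between these effects, and polysomes against Input in control and in GEMIN5 cells. CPM values printed with an SD are scaled by TMM. Events had at least 10 corrected reads in every compared library, a highest PSI of at least 5 and a lowest of at most 95. They were tested with limma 3.58.1 (trend and robust) on log2 odds with 0.5 added to each read number, 1 adjustment over all event types, and counted by a size rule (difference of at least 15 PSI points and a gap of at least 5 between group ranges). Overlaps were tested with Fisher's exact test. Of 25 gene lists, 23 were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), also with an estimated correlation and with fry. The lists of nuclear-retained RNAs and snoRNA host genes had too few members in the count table and were left out. No call of camera with the preset correlation held with an estimated correlation.

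Library measures were compared with exact two-sided permutation tests in SciPy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), with figures by matplotlib 3.10.9. Spliced reads by distance were the exclusion reads of 26135 introns matched to 1 principal transcript per gene, scaled to the total gene counts of each library (no TMM) with 1 added. Intervals of counts and shares are exact, at 95%, and those of ratios of medians are from 2000 bootstrap draws. PCR copies are not independent molecules, so intervals and floors cover counting error only. The floor for a count of 0 was 3 counts per library.

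Named genes were GEMIN5, the 8 called genes with the largest change in each direction (mean CPM of at least 5, no overlap of the groups in simple contrasts, no clone-based symbol), and up to 3 called or 2 abundant members of each list. Named events were the 8 called with the largest PSI difference in each direction and those in splicing factor lists. A part of these is printed. HSPA6, FN1 and other genes named from short lists of calls, the liver genes, and the exon event reads of HFM1 and similar genes were picked after their values were seen. Groups, contrasts, tests, gene lists, naming rules and the main alternatives were chosen before the data were examined.

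The tests were tested on simulated data with 200 changed items. For genes at the Input settings, 28.4%, 80.6% and 100% of changes of 1.5, 2 and 4-fold were recovered, with 5 of 144 calls unchanged, and at the polysome settings 46.3%, 94% and 100%, with 6 of 166 unchanged. Apart from the 200 changes, the simulated GEMIN5 means equalled those of control. The simulation thus held no shift in composition like that of the Input GEMIN5 libraries, and its shares do not carry over to the Input gene calls. For events at the Input settings 1.49%, 29.9% and 66.7% of changes of 10, 20 and 30 PSI points were recovered, with 273 of 338 calls unchanged. At the polysome settings 6 of 57 event calls were unchanged. Simulated event replicates differed by read sampling only, so these shares are not error rates of the real event calls. Replicate pairs within a group differed by more than sampling noise (chi-square per degree of freedom 3.19 to 86.7), so no library was counted as a copy of another.

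Alternatives were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, no filter on low counts, GEMIN5 and mitochondrial genes left out, only the compared groups, a block on replicate number, each library left out in turn, other read and PSI filters, edgeR on event reads and limma on PSI. Scaling to library size only, leaving out pairs of Input control libraries, the liver list or introns, and thinning of event reads were added after the data had been seen.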

Results

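Polyadenylated RNA was sequenced from HEK-293 cells, an established human embryonic kidney line, that were either untreated (control) or transfected with a plasmid expressing GEMIN5. GEMIN5 is an RNA-binding protein that recognises small nuclear RNAs as part of the survival of motor neuron (SMN) complex, which assembles splicing particles. RNA was taken 24 h after transfection from the cytoplasmic lysate (Input) and from sucrose gradient fractions 8 to 12 of 12, which hold mRNAs carrying several ribosomes (Polysome). The series asks whether splicing events that follow changed GEMIN5 levels reach the translated RNA. There were 4 Input control, 3 Input GEMIN5, 4 Polysome control and 4 Polysome GEMIN5 libraries. Gene counts summed to between 11191417 and 18407933 per library. Between 14031 and 14851 genes had counts in a library, and 12197 genes were tested. The control cells were not transfected, so each GEMIN5 comparison is also a comparison of transfected with untransfected cells.

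GEMIN5 itself (ENSG00000082516, chromosome 5, 154887411 to 154938211, minus strand, GRCh38) was measured first. Its normalised level was 13.9 ± 1.71 CPM (SD, n = 4) in Input control and 1430 ± 112 CPM (SD, n = 3) in Input GEMIN5, a log2 fold change of 6.68 (SE 0.21, edgeR quasi-likelihood test, adjusted p = 1.22e-13). In polysomes it was 5.80 ± 1.26 CPM (SD, n = 4) in control and 924 ± 187 CPM (SD, n = 4) in GEMIN5 cells, a log2 fold change of 7.31 (SE 0.22, edgeR adjusted p = 3.46e-14). Every GEMIN5 library lay above every control library in both fractions. The GEMIN5 effect differed between the fractions by 0.63 on the log2 scale (SE 0.25), just short of the threshold (edgeR adjusted p = 0.056). It passed with RLE scaling (0.70, adjusted p = 0.0317), with DESeq2 (adjusted p = 0.00963), with no filter on low counts (adjusted p = 0.0334) and with library size only (1.93, adjusted p = 1.27e-05). It also passed without Input GEMIN5 replicate 2 (0.92, edgeR adjusted p = 0.0127), Polysome control replicate 4 (0.75, 0.0312) or Polysome GEMIN5 replicate 4 (0.77, 0.00722).

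**Figure D1:**
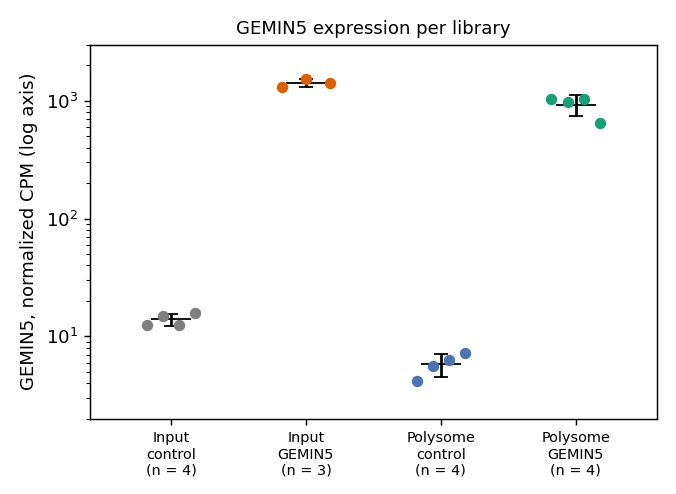
GEMIN5 level in each library as normalised CPM on a log axis, with points for libraries and black bars for the group mean and SD. All 7 GEMIN5 libraries sat between 647 and 1543 CPM, and all 8 control libraries between 4.19 and 15.9 CPM.

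The lysate comparison asked which mRNAs changed in GEMIN5-transfected cells. Ribosomal protein mRNAs rose together in Input GEMIN5, with 78 of 81 higher, 1 lower and 2 not passing, and a median log2 fold change of 2.08. RPS29, RPS21 and the ribosomal protein paralogue RPL22L1 rose by 3.35 (SE 0.22), 3.11 (SE 0.22) and 2.58 (SE 0.17). Nuclear-encoded subunits of the respiratory chain (53 of 63 higher, 3 lower) and replication-dependent histones (42 of 46 higher, 0 lower) rose as well, with medians of 1.59 and 1.85. With library size only the medians of these 3 lists were 0.76, 0.28 and 0.56. Histone values here and below are for RNA captured by a poly(A) kit, and cannot stand for histone RNA without a poly(A) tail. The hnRNP proteins, which package nascent transcripts and regulate splicing, fell, with 22 of 25 lower, 0 higher and a median of −1.38. HNRNPL dropped from 141 ± 8.89 CPM (SD, n = 4) to 17.1 ± 7.40 CPM (SD, n = 3), a log2 fold change of −3.02 (SE 0.33, edgeR adjusted p = 4.83e-07).

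By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6280 genes passed in Input, 3311 higher and 2969 lower. Without Input GEMIN5 replicate 2 the balance turned, to 2105 higher and 3662 lower. Among genes chosen by the size of their change, whose group ranges did not overlap, PDE3A, a cyclic nucleotide phosphodiesterase (ENSG00000172572, chromosome 12, 20368537 to 20688583), rose from 19.9 ± 5.03 to 379 ± 107 CPM (log2 4.25, SE 0.26, edgeR adjusted p = 2.88e-09), although none of its 20 exon events held more than 3 corrected reads in any library. GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176), rose from 1.16 ± 0.168 to 19.7 ± 4.82 CPM (log2 4.05, SE 0.25, edgeR adjusted p = 3.25e-09). The metallothionein MT1F rose by 3.26 (SE 0.19), LCN15 by 3.22 (SE 0.31), the kinase DAPK1 by 3.11 (SE 0.26, 15.0 ± 2.46 to 129 ± 68.6 CPM) and LAMA2 by 3.01 (SE 0.24), the last with at most 3 corrected reads in any of its 75 exon events. MT1F has near-identical relatives, and ribosomal protein and histone genes have copies, so counts of single members are uncertain. Genes that fell included RAVER1, an RNA-binding partner of the splicing regulator PTBP1 (−2.97, SE 0.41), the dynactin subunit DCTN1 (−2.76, SE 0.40), the ribosome assembly factor LTV1 (−2.56, SE 0.32), CPOX (−2.56, SE 0.46), TSPYL1 (−2.51, SE 0.41) and beta-actin, ACTB (ENSG00000075624, chromosome 7, 5526409 to 5563902, 2090 ± 134 to 376 ± 87.7 CPM, log2 −2.48, SE 0.27). MT-ATP8 fell by 2.79 (SE 0.30) and overlaps MT-ATP6, so its reads are uncertain. HSPA6, an inducible HSP70, held 1 to 3 counts per Input control library and 22 to 38 per Input GEMIN5 library, a ratio of 32.8 with TMM scaling (95% counting interval 15.2 to 84.0) and 13.5 with library size only (6.27 to 34.6).

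Of the 23 gene lists fixed before the data were examined, 8 passed in Input by camera with a preset correlation. The ribosomal protein list had a camera adjusted p of 2.66e-30 (adjusted p = 0.65 with an estimated correlation), and 78 members were higher and 2 lower when adjusted over the list alone. The respiratory chain list had a camera adjusted p of 1.40e-15 (adjusted p = 0.65 with an estimated correlation), with 53 higher and 4 lower adjusted over the list alone, and NDUFB1, COX6C and COX7A2 rose by 2.65, 2.41 and 2.37. The histone list, with H4C12 and H2AC18 rising by 2.38 and 1.98, had a camera adjusted p of 6.65e-14 (adjusted p = 0.65 with an estimated correlation) and 42 higher adjusted over the list alone. Of the Sm proteins, which form the ring of small nuclear ribonucleoproteins, and their loading factors, 8 of 12 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 1.00 that was −0.31 under scaling to library size only (camera adjusted p = 0.00924, adjusted p = 0.65 with an estimated correlation). SNRPG, SNRPE and SNRPF rose by 2.51, 2.04 and 1.79. In the hnRNP list (camera adjusted p = 6.98e-07, adjusted p = 0.65 with an estimated correlation) the 22 lower members also passed adjusted over the list alone, among them HNRNPAB (−1.41, SE 0.14). Of 13 SR and TRA2 splicing factors 9 fell and 0 rose, also adjusted over the list alone, with a median of −0.75 (camera adjusted p = 0.00924, adjusted p = 0.65 with an estimated correlation), and TRA2A and SRSF4 stood at −1.88 and −1.73. Of 26 DNA replication genes 13 fell and 3 rose, with 14 lower adjusted over the list alone (camera adjusted p = 0.0224, adjusted p = 0.891 with an estimated correlation). Of 17 unfolded protein response genes 9 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.04998, adjusted p = 0.65 with an estimated correlation). The endoplasmic reticulum chaperones PDIA4 and CALR stood at −1.59 and −1.54, while DDIT3, a stress-induced transcription factor, rose by 2.58.

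In the SMN complex, the home of GEMIN5, 3 of the 8 other members rose and 3 fell, the same numbers adjusted over the list alone, and the list did not pass. GEMIN6 rose by 1.46 (SE 0.15, edgeR adjusted p = 2.86e-07), but by 0.16 with edgeR adjusted p = 0.234 under scaling to library size only. The log2 fold change of SMN1, which shares reads with its near-identical copy SMN2, was −1.21 (SE 0.16). GEMIN2 rose by 0.60 (SE 0.11, edgeR adjusted p = 0.000164), which turned to −0.69 under scaling to library size only and missed the threshold without Input GEMIN5 replicate 2 (0.31, edgeR adjusted p = 0.0928). The other lists that did not pass had the same counts adjusted over the list alone. Numbers higher and lower were 9 and 10 of 34 proteins specific to single small nuclear ribonucleoproteins, 8 and 8 of 19 other mRNAs with a 5′ terminal oligopyrimidine (TOP) tract, and 7 and 10 of 33 translation initiation factors. Among TOP mRNAs TPT1 and EEF1B2 rose by 1.44 and 1.58 and EEF2 fell by 1.42. TPT1 did not pass under scaling to library size only (0.13, edgeR adjusted p = 0.221). They were 4 and 4 of 15 interferon response genes, 4 and 1 of 7 NF-kB targets, 3 and 4 of 24 integrated stress response genes, 3 and 8 of 18 heat shock genes and 0 and 7 of 22 immediate early genes, with MYC at −1.34. Further lists gave 4 and 5 of 17 p53 targets, 6 and 6 of 22 cholesterol synthesis genes, 4 and 10 of 22 G2/M genes, 3 and 2 of 13 mitochondrially encoded mRNAs, 1 and 6 of 12 mRNAs with regulatory upstream open reading frames (uORFs), and 3 and 1 of 8 markers of other cell types. Median and mean differed in sign for the initiation factors (0.04 and −0.16) and for the p53 targets (−0.08 and 0.16), and the marker list had a mean of −1.41 but a camera direction towards higher values.

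The libraries of Input GEMIN5 also differed in composition. Ribosomal protein genes took 34.9% ± 0.529 (SD, n = 4) of counts in Input control and 58.5% ± 2.62 (SD, n = 3) in Input GEMIN5, and mitochondrially encoded genes 4.22% ± 0.388 and 1.77% ± 0.310. Over 906 genes, the median log2 ratio of spliced reads at the 3′-most against the 5′-most junctions was 0.54 ± 0.0287 (SD, n = 4) in Input control and 1.59 ± 0.0643 (SD, n = 3) in Input GEMIN5. The groups did not overlap in any of these measures, and each gave an exact two-sided permutation p of 0.0571, the smallest that 4 against 3 libraries allow (0.0878 after adjustment over 20 tests). In genes other than ribosomal protein genes, the median log2 change of spliced reads, scaled to the total counts of each library, was −0.07 at junctions 150 to 300 nt from the 3′ end and −1.26 at 1500 to 2000 nt. It was −1.05 at 6000 nt or more. The TMM factors that scaled the libraries were 0.990 ± 0.0281 (SD, n = 4) and 0.406 ± 0.0723 (SD, n = 3). Scaling to library size only left the median gene at −1.29 and gave 605 higher and 9270 lower genes, and the fold changes above are relative to the median gene.

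**Figure D2:**
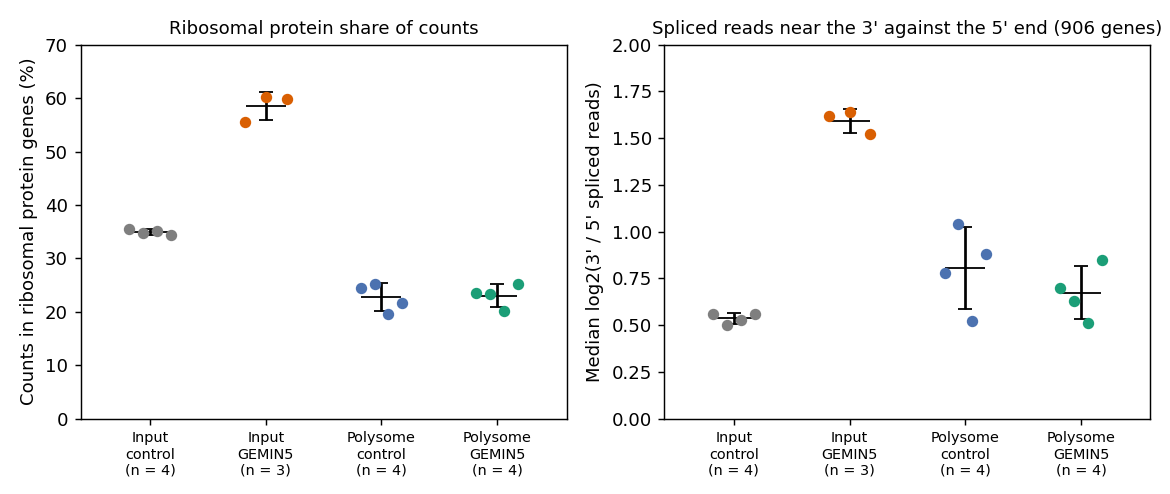
Left, percent of counts in ribosomal protein genes per library; right, median log2 ratio of spliced reads at the 3′-most against the 5′-most junctions over 906 genes; points are libraries, black bars the group mean and SD. Input GEMIN5 stood apart in both, at 55.5% to 60.3% and 1.52 to 1.64, while both polysome groups overlapped.

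**Figure D3:**
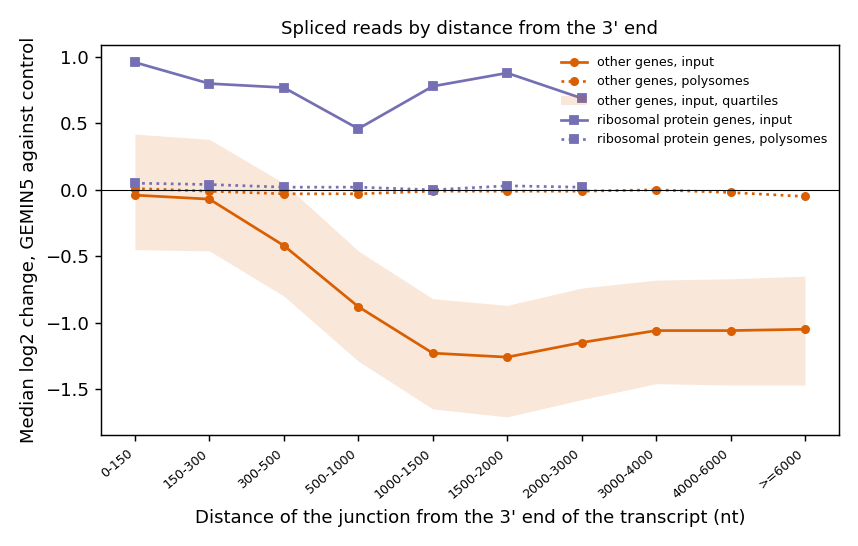
Median log2 change of spliced reads, scaled to total counts only, GEMIN5 against control, by distance of the junction from the 3′ end in nt, with quartiles shaded for genes other than ribosomal protein genes in Input (bins of at least 20 junctions). In Input these other genes ran from −0.04 at 0 to 150 nt to −1.26 at 1500 to 2000 nt and back to −1.05 at 6000 nt or more. Ribosomal protein genes stayed between 0.46 and 0.96, while polysome medians lay between −0.05 and 0.05. From 1000 to 3000 nt the ribosomal protein bins held 24 to 32 junctions of 10 to 13 genes. Distances are those of 1 annotated transcript per gene. Whether the cells used that 3′ end was not tested, so these far bins do not show that ribosomal protein mRNAs escaped the loss.

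In polysomes, few genes changed with GEMIN5. GDF15 rose from 0.682 ± 0.218 to 4.15 ± 0.977 CPM (SD, n = 4 each; log2 2.59, SE 0.26, edgeR adjusted p = 2.28e-05). HSPA6 held 0 to 3 counts per control library and 27 to 50 per GEMIN5 library, a ratio of 26.9 with TMM scaling (95% counting interval 12.1 to 74.3). CRIP2 rose by 1.26 (SE 0.20, edgeR adjusted p = 0.00653), MT1F by 1.01 (SE 0.17, edgeR adjusted p = 0.00988) and HMOX1, the haem-degrading oxygenase, by 0.93 (SE 0.16, edgeR adjusted p = 0.00921). DDIT3, which had risen in Input, did not pass (0.66, SE 0.25, edgeR adjusted p = 0.655). Among plasma protein genes of liver, FGB, FGG and C3 passed as lower. ALB, which encodes serum albumin, held 448 to 584 counts per Polysome control library and 0 to 3 per Polysome GEMIN5 library but did not pass (edgeR adjusted p = 0.166).

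The edgeR test called 49 genes in polysomes, 10 higher and 39 lower, against 706 at an unadjusted p under 0.05. The number depended on single libraries: it was 90, 24, 26 and 16 without Polysome control replicates 1 to 4 in turn, and 12, 9, 17 and 31 without Polysome GEMIN5 replicates 1 to 4. The MT1F call was lost without Polysome control replicate 4 (edgeR adjusted p = 0.0543) and with only the 2 groups compared (0.118). That of HMOX1 was lost without Polysome GEMIN5 replicate 1 (0.0609) or 2 (0.0571). CCNL1, a cyclin of splicing kinases, rose by 0.69 (SE 0.13, edgeR adjusted p = 0.0238) but lost the call without Polysome control replicate 2 or 3 (0.0649 and 0.0610) or Polysome GEMIN5 replicate 1, 2 or 3 (0.0706, 0.138 and 0.0761). It was also lost with only the 2 groups compared (0.067) and with library size only (0.0828). Of the 10 higher genes, 8 were also higher in Input (CRIP2, FES, GDF15, GEMIN5, HSPA6, MT1F, NUPR1 and ZNF79), where independent lists would share 2.71 (Fisher's exact test, two-sided p = 0.000761). Of the 39 lower genes 12 were also lower in Input against 9.49 (Fisher's exact test, two-sided p = 0.352). They were ADH1B, AMBP, C3, CP, CYP2E1, FGB, FGG, FN1, ORM1, PCK1, SERPINC1 and SPP1.

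Of the 39 lower genes, 10 were on a list of 22 liver genes (21 tested), which was written after some of them had been seen. The others included the extracellular matrix gene FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436073), which fell from 10.1 ± 2.69 to 1.62 ± 0.171 CPM (SD, n = 4 each; log2 −2.62, SE 0.40, edgeR adjusted p = 0.00547), and the blood cell genes LYZ, S100A9, CD74, HLA-DRA and HBB. Many more of these others, such as CP, SERPINC1, F5, VTN, C4BPA, AGT, MAT1A and HGD, are also known as genes of liver. Whether FN1 fell for the same reason as the liver genes was not tested. ALB counts were 0, 0, 588 and 414 in Input control libraries 1 to 4 and 0 in each Input GEMIN5 library, and a count of 0 there allows up to 0.163 to 0.174 CPM. The liver genes together held 1403 to 1844 counts per Polysome control library and 6 to 15 per Polysome GEMIN5 library, where 4 to 7 of the 22 had any count. Without the liver list 39 genes passed, 9 higher and 30 lower, a set that still holds these liver and blood genes.

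**Figure D4:**
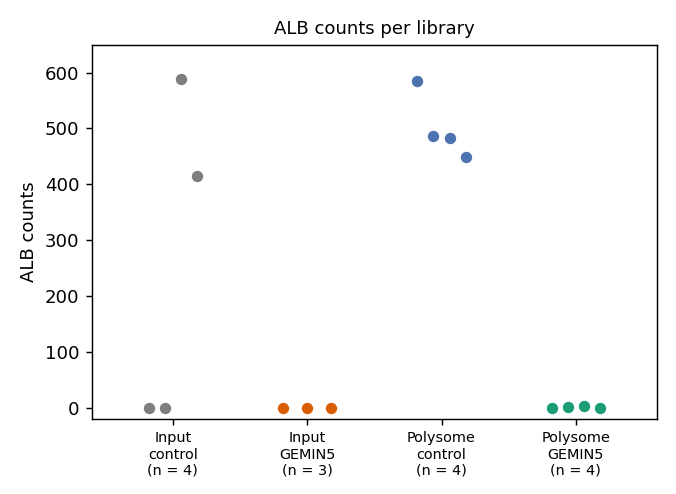
ALB counts in each library by group, each point a library. Input control libraries 3 and 4 and all 4 Polysome control libraries lay between 414 and 588, and every other library between 0 and 3.

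Most lists had 0 members past the threshold in polysomes over all genes. Ribosomal protein genes had a median log2 fold change of 0.01 with 0 of 81 called (RPL8 0.01, SE 0.16), 22.7% ± 2.64 of counts in control and 23.0% ± 2.09 in GEMIN5 cells (SD, n = 4 each, exact two-sided permutation p = 0.914). By camera, 7 lists passed. For 13 mitochondrially encoded mRNAs (median 0.49, camera adjusted p = 2.27e-08, adjusted p = 0.443 with an estimated correlation) none passed over all genes and 6 were higher adjusted over the list alone, with MT-CO3 at 0.33 (SE 0.25). For markers of other cell types 1 of 8 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 4.33e-08, adjusted p = 0.0542 with an estimated correlation). In the hnRNP list (median −0.30, camera adjusted p = 0.000169, adjusted p = 0.87 with an estimated correlation) and the histone list (median −0.20, camera adjusted p = 0.000542, adjusted p = 0.87 with an estimated correlation) 0 members passed, also adjusted over the list alone. HNRNPA1 stood at −0.56 (SE 0.21, edgeR adjusted p = 0.651), which passed only without Polysome control replicate 1 (−0.78, edgeR adjusted p = 0.0287). H4C12 stood at −0.78 (edgeR adjusted p = 0.125), which passed only without Polysome GEMIN5 replicate 4 (−1.08, edgeR adjusted p = 0.00313). The uORF list had a median of 0.20 (camera adjusted p = 0.000542, adjusted p = 0.138 with an estimated correlation), with ATF4, the translationally induced stress factor, at 0.12 (SE 0.16). Medians were −0.09 for the snRNP-specific proteins (camera adjusted p = 0.0238, adjusted p = 0.87 with an estimated correlation) and −0.08 for other TOP mRNAs (camera adjusted p = 0.0369, adjusted p = 0.87 with an estimated correlation), and in these 3 lists 0 members passed, also adjusted over the list alone.

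Polysome association was compared between conditions as the difference between the GEMIN5 effect in polysomes and that in Input. Ribosomal protein mRNAs were lower in this difference, with 78 of 81 lower and 0 higher, led by RPS29 (−3.29, SE 0.29, edgeR adjusted p = 1.19e-06) and RPS21 (−3.00, SE 0.29). Histones (40 of 46 lower) and respiratory chain subunits (50 of 63 lower, 2 higher) fell with them, H4C12 by 3.17 (SE 0.30). The hnRNP list rose, with 16 of 25 higher and 0 lower, and HNRNPL and RAVER1 rose by 2.69 (SE 0.41) and 3.29 (SE 0.48). These lists mirrored Input, where their levels had moved, while polysome medians stayed between −0.30 and 0.01. The Input GEMIN5 libraries behind them had a 3′ to 5′ log2 ratio of spliced reads of 1.59, against 0.54 in Input control.

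In all, 4553 genes passed edgeR's test of this difference, 2058 higher and 2495 lower. Without Input GEMIN5 replicate 2 the balance turned, to 2674 higher and 1427 lower. MT-ATP8 and LTV1 rose by 3.61 (SE 0.39) and 2.58 (SE 0.40), and PDE3A fell by 3.50 (SE 0.33). TTC16 fell by 3.42 (SE 0.58) on counts with at most 1 corrected read in any of its 13 exon events. Scaling to library size only left the median gene at 1.27 and gave 8412 higher and 387 lower. By camera, 9 lists passed. They were ribosomal proteins (median −2.05, adjusted p = 0.359 with an estimated correlation, 78 lower adjusted over the list alone), histones (−2.05, adjusted p = 0.359 with an estimated correlation, 43 lower adjusted over the list alone) and the respiratory chain (−1.60, adjusted p = 0.359 with an estimated correlation, 51 lower and 3 higher adjusted over the list alone). The Sm list had 8 of 12 lower and 1 higher, also adjusted over the list alone, with a median of −1.07 that was 0.24 under scaling to library size only (adjusted p = 0.359 with an estimated correlation). The hnRNP list (median 1.02, adjusted p = 0.681 with an estimated correlation) had 18 higher adjusted over the list alone. With library size only the medians of the ribosomal, histone, respiratory chain and hnRNP lists were −0.72, −0.73, −0.29 and 2.26. The SR list had 7 of 13 higher and 0 lower (adjusted p = 0.609 with an estimated correlation), and DNA replication 8 of 26 higher and 2 lower (adjusted p = 0.85 with an estimated correlation). The uORF list had 6 of 12 higher and 1 lower (adjusted p = 0.359 with an estimated correlation), and markers of other cell types 3 of 8 lower (adjusted p = 0.461 with an estimated correlation). These 4 lists had the same counts adjusted over the list alone.

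Polysomes were also compared with Input within each condition. In control cells ribosomal protein and other TOP mRNAs were lower in polysomes than in the lysate: 70 of 81 ribosomal protein genes fell and 1 rose (median −0.99), and 14 of 19 other TOP mRNAs fell and 0 rose (median −1.04). The log2 fold changes of RPS2, RPSA and TPT1 were −2.46 (SE 0.20), −2.05 (SE 0.17) and −1.86 (SE 0.16), while translation initiation factors went both ways and did not pass as a list. Of 33 initiation factors 9 were higher and 12 lower, also adjusted over the list alone (median −0.12, camera adjusted p = 0.478), with EIF3L at −1.49 (SE 0.13) and EIF4H at 1.68 (SE 0.13). All 13 mitochondrially encoded mRNAs, which are translated inside mitochondria, fell, with a median of −3.19, and MT-ND3 and MT-CO2 stood at −4.18 (SE 0.21) and −3.65 (SE 0.23). The ferritin subunits FTL and FTH1, whose translation is repressed when iron is low, stood at −4.17 (SE 0.21) and −4.17 (SE 0.20). They fell from 1210 ± 33.7 to 66.9 ± 13.1 CPM and from 3020 ± 157 to 168 ± 31.5 CPM (SD, n = 4 each). Histones rose, with 25 of 46 higher, 0 lower and a median of 0.85, H1-4 by 2.12 (SE 0.21) and H3C14 by 1.65 (SE 0.20).

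The edgeR test called 5265 genes in control cells, 2937 higher and 2328 lower in polysomes, and 6492 higher and 560 lower under scaling to library size only, which left the median gene at 0.54. Ribosomal protein genes took 34.9% ± 0.529 of Input control counts and 22.7% ± 2.64 of Polysome control counts (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and 0.0878 after adjustment over 20 tests). HFM1, a helicase gene of meiosis (ENSG00000162669, chromosome 1, 91260766 to 91404856), rose by 5.53 (SE 0.31, edgeR adjusted p = 7.41e-10) from 195 ± 64.5 to 9020 ± 2890 CPM (SD, n = 4 each), SLCO5A1 by 5.32 (SE 0.35) and PDE3A by 4.09 (SE 0.25). Exon events of these 3 genes held at most 5, 6 and 3 corrected reads in any library. SKI rose by 3.30 (SE 0.28), and GEMIN5 fell by 1.26 (SE 0.18, edgeR adjusted p = 2.62e-05).

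By camera, 11 lists passed in control cells: ribosomal proteins (adjusted p = 8.66e-24, adjusted p = 0.39 with an estimated correlation), mitochondrially encoded mRNAs (adjusted p = 1.16e-13, adjusted p = 0.245 with an estimated correlation), other TOP mRNAs (adjusted p = 1.10e-09, adjusted p = 0.245 with an estimated correlation) and histones (adjusted p = 5.58e-07, adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, 70, 13 and 15 members of the first 3 were lower and 27 histones higher. Of 22 G2/M genes 15 were lower, also adjusted over the list alone, with KIF20A at −1.65 (camera adjusted p = 1.89e-06, adjusted p = 0.39 with an estimated correlation). The other 6 lists had negative medians that turned positive under scaling to library size only. Of 34 snRNP-specific proteins 14 fell and 4 rose, also adjusted over the list alone, with PRPF8, the core of the spliceosome, at −2.36 (SE 0.13; adjusted p = 0.314 with an estimated correlation). Heat shock genes had 8 of 18 lower and 1 higher, 9 and 1 adjusted over the list alone (adjusted p = 0.413 with an estimated correlation), and cholesterol synthesis genes 10 of 22 lower and 2 higher, 11 and 2 adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Respiratory chain genes had 15 of 63 lower and 3 higher, 13 and 3 adjusted over the list alone (adjusted p = 0.656 with an estimated correlation). Unfolded protein response genes had 7 of 17 lower and 2 higher, also adjusted over the list alone, with HSP90B1 at −1.59 (adjusted p = 0.39 with an estimated correlation). DNA replication genes had 15 of 26 lower and 5 higher, 15 and 6 adjusted over the list alone (adjusted p = 0.56 with an estimated correlation).

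In GEMIN5 cells, 80 of 81 ribosomal protein genes were lower in polysomes than in Input and 1 higher, and RPS29 fell by 4.50 (SE 0.23). The 3′ to 5′ log2 ratio of spliced reads was 1.59 in Input GEMIN5 and 0.67 in Polysome GEMIN5. FTL and FTH1 stood at −5.85 (SE 0.23) and −5.19 (SE 0.22), and 12 of 13 mitochondrially encoded mRNAs fell. RAVER1 and QKI, an RNA-binding splicing regulator, rose by 4.58 (SE 0.40) and 4.55 (SE 0.38), and HFM1 and SLCO5A1 by 4.64 (SE 0.34) and 4.77 (SE 0.38). TTC16 and MATN1 stood at −8.05 (SE 0.31) and −6.45 (SE 0.37), with at most 1 and 2 corrected reads in any exon event. GEMIN5 stood at −0.63 (SE 0.17, edgeR adjusted p = 0.0035), which turned to 1.2 under scaling to library size only and missed the threshold without Input GEMIN5 replicate 2 (−0.44, edgeR adjusted p = 0.0548).

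The edgeR test called 8247 genes in GEMIN5 cells, 3980 higher and 4267 lower, and 10310 higher and 465 lower under scaling to library size only, which left the median gene at 1.78. Of the 10 lists that passed by camera, ribosomal proteins (median −3.02), mitochondrially encoded mRNAs (−2.46), hnRNP proteins (0.96, 19 of 25 higher), SR proteins (1.14, 10 of 13 higher, 1 lower) and the uORF list (1.08, 8 of 12 higher, 1 lower) kept the sign of their median under that scaling. The respiratory chain (−1.75, 57 of 63 lower, 1 higher), histones (−1.35, 34 of 46 lower, 1 higher), Sm proteins (−1.37, 9 of 12 lower, 1 higher), snRNP-specific proteins (−0.47, 18 of 34 lower, 3 higher) and other TOP mRNAs (−1.34, 13 of 19 lower, 2 higher) turned positive under it. Adjusted over the list alone, 80, 12, 59, 35, 9, 18 and 13 members of the ribosomal, mitochondrial, respiratory, histone, Sm, snRNP-specific and TOP lists were lower, and 20, 10 and 8 of the hnRNP, SR and uORF lists higher. All 10 calls were lost when the correlation was estimated, with adjusted p = 0.737 with an estimated correlation for hnRNP proteins and adjusted p = 0.516 with an estimated correlation for the other 9.

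The splicing question was addressed with the percent spliced in (PSI), the share of an event's reads that include an exon, splice site or intron. Among the events called in Input, exons were mostly less included and introns mostly more retained in the GEMIN5 libraries. An exon of CIRBP, a cold-inducible RNA-binding protein (HsaEX1008821, chromosome 19, 1272427 to 1272523, hg38), dropped from 72.8% ± 2.76 (SD, n = 4) to 19.7% ± 4.43 (SD, n = 3; limma adjusted p = 0.000206). One of TPGS2 (HsaEX1041701, chromosome 18, 36796809 to 36797050) dropped from 77.5% ± 2.5 to 24.4% ± 4.77. An intron of the checkpoint kinase gene CHEK2 (HsaINT1007614, chromosome 22, 28719486 to 28721517) went from 28.8% ± 6.36 to 89.5% ± 4.71 (limma adjusted p = 0.000238). One of ZNF330 (HsaINT0186882, chromosome 4, 141222492 to 141224486) went from 10.1% ± 2.42 to 80.3% ± 7.83. Some exons went the other way, such as one of NELFA (HsaEX0071505, chromosome 4, 2006998 to 2007199), from 15.3% ± 1.99 to 86.5% ± 18.5 (limma adjusted p = 0.000518).

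Of 11930 events tested in Input, limma called 1343 in 888 genes, 569 with higher and 774 with lower PSI, by a median of 6.55 PSI points. Called exons were mostly lower (600 of 733) and called introns mostly higher (251 of 281). In simulated data with the Input read numbers, 273 of the 338 events that this test called were unchanged, against 0 of 52 with edgeR on inclusion and exclusion reads. Replicates there differed by read sampling only, so neither share is an error rate of the calls on real data. On the real data edgeR called 693 events (59 exons higher, 380 lower), and limma with reads thinned to 1 total per event called 402. A difference of at least 15 PSI points with group ranges at least 5 points apart was met by 396 events, and by 599 without Input GEMIN5 replicate 1. In splicing factor genes, an SRSF10 intron (HsaINT1042962, chromosome 1, 23975078 to 23978712) rose from 5.76% ± 2.20 to 26.7% ± 1.48, and a PRPF31 intron (HsaINT0132572, chromosome 19, 54118634 to 54121859) from 1.84% ± 0.293 to 14.5% ± 1.77. An HNRNPA3 intron rose from 0.757% to 7.26%, which did not pass with thinned reads (limma adjusted p = 0.0918). An exon of HNRNPH3 (HsaEX0030298, chromosome 10, 68337858 to 68337996) fell from 97.9% ± 0.299 to 79.9% ± 3.49. One of the DNA repair gene FANCI (HsaEX0024810, chromosome 15, 89300300 to 89300385) fell from 56.4% ± 4.05 to 9.16% ± 3.10. No event of GEMIN5 was among those tested.

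**Figure D5:**
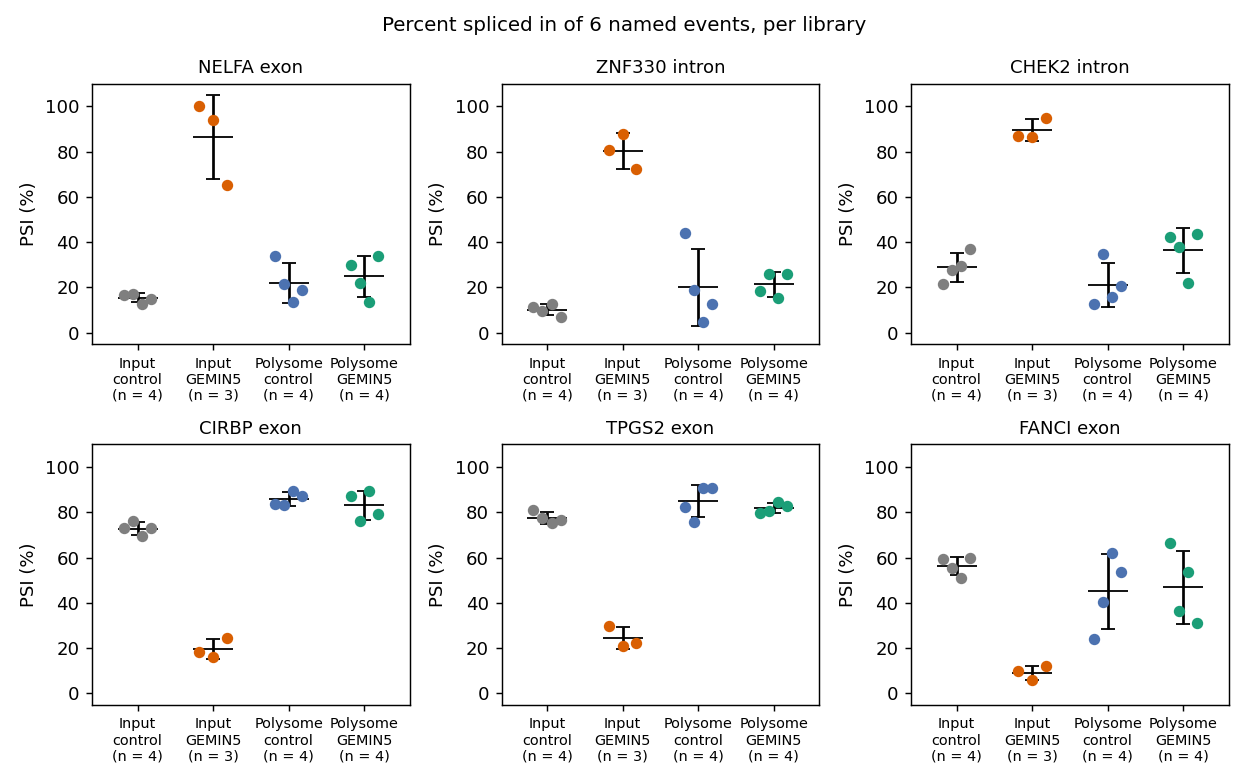
PSI in percent of 6 events per library and group; points are libraries with at least 10 corrected reads, black bars the group mean and SD. Input GEMIN5 stood apart from Input control in each (CIRBP exon 19.7% against 72.8%, CHEK2 intron 89.5% against 28.8%), while the polysome groups overlapped.

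In polysomes the same comparison called 0 of 17485 events by limma, with 1006 at an unadjusted p under 0.05 and 4 called by edgeR. An exon of DBNL (HsaEX0018568, chromosome 7, 44051830 to 44051942) stood at 100% in every control library and 94.2% ± 2.93 (SD, n = 4) in GEMIN5 cells (limma adjusted p = 0.0576), and an exon of HPS4 (HsaEX0030427, chromosome 22, 26457859 to 26457967) at 76.1% ± 5.35 and 100% (limma adjusted p = 0.081), neither of which passed. DBNL passed with at least 20 reads (0.0411), with no filter on PSI range (0.0201) and with thinned reads (0.0373), and HPS4 with no filter on PSI range (limma adjusted p = 0.037). The CIRBP exon stood at 85.9% ± 2.97 and 83.1% ± 6.30 (SD, n = 4 each). The size rule was met by 17 events, and by 37 to 49 when any 1 library was left out: 49, 37, 42 and 39 without control replicates 1 to 4 and 49, 41, 49 and 46 without GEMIN5 replicates 1 to 4. At the polysome read numbers, simulated changes of 10, 20 and 30 PSI points were recovered in 0%, 25.4% and 51.5% of events by limma. By edgeR they were recovered in 4.48%, 38.8% and 66.7%. The simulated replicates differed by read sampling only, so recovery in real events can be lower.

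With 0 polysome calls no overlap with the Input calls was possible, so the Input calls among the 7972 events tested in both were compared by sign and size. Of 259 higher events in Input 51.7% had the same sign in polysomes, against 47.8% of all events, and of 362 lower events 59.7% against 52.2%. Their median PSI difference was 18 and −17.1 points in Input but 0.227 and −0.870 in polysomes. These events were chosen by their Input change and had to meet the PSI filter in both fractions, so part of the contrast in size follows from that choice. They are a part of the 1343 Input calls, whose median size was 6.55. A test of whether the GEMIN5 effect differed between the fractions called 246 of 12697 events, 117 higher and 129 lower in polysomes relative to Input. Called exons were mostly higher (93 against 26) and called introns mostly lower (73 against 6), the reverse of Input, whose libraries both tests share. The CIRBP and TPGS2 exons differed by 50.4 and 50.1 PSI points, and the ZNF330 intron and NELFA exon by −68.7 and −68.3. The ZNF330 call was lost without Polysome GEMIN5 replicate 3 (limma adjusted p = 0.0503). With thinned reads TPGS2, ZNF330 and NELFA lost the call (limma adjusted p = 0.0512, 0.175 and 0.0812). With Input control 1 and 2 left out all 4 did (CIRBP 0.0586, TPGS2 0.0752, ZNF330 0.0899, NELFA 0.0752), and with 3 and 4 left out ZNF330 and NELFA did (0.0834 and 0.0761). The count of 246 was 43 with thinned reads, and 39 and 5 with Input control 3 and 4 or 1 and 2 left out. It was 138, 115, 115 and 124 without Input control replicates 1 to 4 and 133 without Input GEMIN5 replicate 2. It was 117, 126 and 146 without Polysome control replicates 1, 2 and 4, and 118 and 75 without Polysome GEMIN5 replicates 2 and 3.

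Between polysomes and Input of control cells, limma called 9 of 16106 events, 4 higher and 5 lower, against 1499 at an unadjusted p under 0.05. An intron of UBAP2L (HsaINT0176197, chromosome 1, 154259031 to 154259947) fell from 26.7% ± 5.05 to 1.83% ± 1.82 (SD, n = 4 each) and one of ELOB (HsaINT1012484, chromosome 16, 2777128 to 2777236) from 8.34% ± 0.488 to 1.59% ± 0.0493 (limma adjusted p = 0.00416 for both). Both calls were lost with Input control 3 and 4 left out (limma adjusted p = 0.182 for both) or 1 and 2 left out (0.142 and 0.127), and that of ELOB also with only the 2 groups compared (0.132). An exon of the histone chaperone NASP (HsaEX0041710, chromosome 1, 45600385 to 45600457) rose from 4.31% ± 1.81 to 22.4% ± 8.43 (limma adjusted p = 0.0277) and an intron of the splicing factor RBM39 (HsaINT0138532, chromosome 20, 35729528 to 35731940) from 6.42% ± 0.05 to 19.4% ± 4.58 (limma adjusted p = 0.0491). The NASP call was lost without Input control replicate 1, 2, 3 or 4 (0.0866, 0.0627, 0.0749 and 0.0531) or Polysome control replicate 1 or 4 (0.0717 and 0.0834). That of RBM39 was lost without Input control replicate 1, 2, 3 or 4 (0.130, 0.173, 0.118 and 0.115) or Polysome control replicate 1, 2 or 4 (0.142, 0.103 and 0.0841). The count was 4, 4, 5 and 4 without Input control replicates 1 to 4 and 5 and 4 without Polysome control replicates 1 and 4.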

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

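The tests of scaling, of the transfection response, of distance within ribosomal protein genes and within single genes, of ALB in Input control, of PSI near its limits, and all regroupings of the samples were chosen after the results had been seen; those of the 3′ loss over all genes, of liver RNA, of read numbers and of exon distance were written before.

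Short mRNAs and ribosomal protein mRNAs rose and long mRNAs fell in Input GEMIN5, relative to each other. The fall was not steady with length. Scaled to total counts only, the median was −1.44 for genes of 3000 to 4000 nt but −1.10 for those of at least 6000 nt. The median of ribosomal protein genes was 2.12 under TMM and 0.78 with library size only (bootstrap over genes 0.63 to 0.93). Both scalings are relative, and ribosomal protein genes took 34.9% of counts in Input control and 58.5% in Input GEMIN5. A fall of other mRNAs alone could give such values, so the test cannot decide on scaling between libraries. For long mRNAs scaling cannot be told apart either. The median of 6021 other genes of at least 2000 nt was −1.31 with library size only but −0.25 (−0.27 to −0.23) under TMM. The loss of spliced reads far from the 3′ end was present inside single genes, where the change at junctions at least 2000 nt away minus that within 500 nt had a median of −1.09 on the log2 scale over 77 genes (0.25 in polysomes, with 5 of 77 genes lower), so a loss of 5′ reads is a candidate cause of the lower counts of long mRNAs. For ribosomal protein genes that loss was argued against as the whole cause only among genes with junctions within 300 nt of the 3′ end. At those junctions the difference to other genes was 0.96, which was 93.3% (bootstrap 64.6 to 116.2) of the 1.03 in the counts of the same genes. The bootstrap drew junctions and genes as independent and drew no libraries, so the interval leaves out the spread between libraries. In the counts of all genes the difference was 1.98, of which 0.96 was 48.4% (39.1 to 55.1). There, loss of reads and a response of the cells to GEMIN5 plasmid transfection cannot be told apart. The response is also confounded with the untreated control, with a ribosomal protein median of 0.01 in polysomes.

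Liver transcripts were present in Input control libraries 3 and 4 and in every Polysome control library and nearly absent elsewhere. The profile over 22 liver genes was alike in the 6 libraries that held them, with a lowest Pearson correlation of 0.96 over 15 pairs, which is consistent with RNA of liver mixed into some control libraries. A loss of liver transcripts through GEMIN5 was argued against, because 2 Input control libraries of untreated cells held 0 ALB counts. Blood cell genes such as HBB and LYZ were among the other lower polysome genes, and the origin of the RNA was not tested further.

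Exons were mostly less included and introns more retained among the Input splicing calls. Fewer reads in Input GEMIN5 together with the 0.5 added to each read number was argued against as the whole cause, since at least 72.5% of called exons were lower in each of 10 thinned draws and 72.1% in the draw with 402 calls. Loss of reads far from the 3′ end could not be judged. Of 133 called exons within 1000 nt of the 3′ end 97.7% were lower. Of these 133, 87 had a mean PSI above 95 in Input control and could hardly rise, but all 26 of middle PSI fell too. Spliced reads of genes other than ribosomal protein genes already had a median change of −0.88 at 500 to 1000 nt. Such exons are therefore not free of the loss. PSI near its limits was argued against only for called exons of middle PSI, with a mean over 25 and up to 75 over all Input libraries. Of these 81.2% were lower (95% interval 73.4 to 87.6), and 80.2% by the mean of Input control alone. The share over all Input libraries was 7.8% up to 5, 47.6% at 5 to 25, 88.8% at 75 to 95 and 96.9% above 95. Outside the middle the share rose with PSI, so the limits were not argued against there. By Input control 413 of 733 called exons were above 95. Of exons not matched to a principal transcript 52.2% were lower. A biological change of splicing remains a hypothesis found on the same data, confounded with transfection. In the simulation, where replicates differed by read sampling only, 273 of 338 calls of this test were unchanged.

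Among 171 groups of 4 values examined, 8 had a sample far from the others, where chance gives 8.6. The TMM factor of Input control 4 was 1.032 (others 0.971 to 0.979). DDIT3 in Input control 2 was 5.677 CPM (others 12.20 to 13.26), and PDIA4 in the same library 216.4 CPM (others 194.9 to 198.5). GEMIN5 in Polysome GEMIN5 4 was 646.5 CPM (others 981.9 to 1034). CRIP2 was 3.102 CPM in Polysome control 4 (others 4.583 to 4.779) and 7.797 CPM in Polysome GEMIN5 3 (others 10.94 to 11.51). PSI was 6.35% in Input control 3 for the RBM39 intron (others 6.45%) and 4.55% in Polysome control 1 for the UBAP2L intron (others 0.79% to 1.12%). The GEMIN5 effect differed between polysomes and Input by a test of the difference for 4553 genes and 246 events.

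Other splits of the same libraries into groups of the same sizes were counted, the real split included. As many genes as in the real split were called in 1 of 35 splits for Input (highest other 2811), 1 of 35 for control polysomes against Input (0) and 1 of 35 for GEMIN5 polysomes against Input (6939). That share of 0.0286 is the smallest that 35 splits allow and was not adjusted over the tests. It argues against a grouping by chance there without excluding it. For the difference between fractions the number was 2 of 60 (real 4553, highest other 5077). The splits beside the real one were a random draw from those possible, too few to exclude chance. The higher split kept the Input groups and regrouped the polysome libraries, so chance was not excluded for the polysome grouping. For polysomes 4 of 35 splits called as many genes (highest other 3017, with Polysome control 1 and 2 beside Polysome GEMIN5 1 and 4), so it was not excluded. As many lists passed in 4 of 35 splits for Input (highest other 8), 24 of 35 for polysomes (13), 7 of 60 for the difference (12), 14 of 35 in control (16) and 5 of 35 in GEMIN5 cells (11), so chance was excluded for none. As many events were called in 1 of 35 splits for Input (4), 1 of 35 for control (2) and 2 of 60 for the difference (438, from that same split of the libraries), but in 35 of 35 for polysomes (1). The size rule was met as often in 1 of 35 splits for Input (81) and 18 of 35 for polysomes (31).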

How the results depend on the processing

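The alternatives with library size only, pairs of Input control libraries, the liver list or introns left out, and thinned reads were chosen after the data had been seen. Of 1702 values of named genes under alternatives 1674 kept their direction and side of the threshold, 16 missed it, 10 passed it and 2 reversed; of 358 values of named events 308 kept both, 46 missed it, 4 passed it and 0 reversed. The 2 reversed values were GEMIN2 in Input (−0.69) and GEMIN5 in polysomes against Input of GEMIN5 cells (1.2), both with library size only, which moves every gene alike. With library size only 9875 genes passed in Input and 8799 for the difference between fractions, and DESeq2 called 87 genes in polysomes. With an estimated correlation 0 lists passed in Input, 0 in polysomes, 0 for the difference, 0 in control and 0 in GEMIN5 cells, and fry called 1 list in polysomes and 18 in GEMIN5 cells. Every list that camera called in Input also passed by fry, up to DNA replication (fry adjusted p = 0.0143). So did those for the difference except DNA replication (fry adjusted p = 0.153), and those in control except the respiratory chain (fry adjusted p = 0.102). Fry tests the members alone, without comparing them with other genes.

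Event calls in Input were 763 with at least 20 reads, 34759 with no filter on PSI range, 693 by edgeR, 512 with only the 2 groups compared, 402 with thinned reads, 501 with Input control 3 and 4 left out and 490 with 1 and 2 left out. In polysomes they were 1 with at least 20 reads, 17 with no filter on PSI range, 4 by edgeR and 1 with thinned reads. For the difference they were 154 with at least 20 reads, 25298 with no filter on PSI range, 107 by edgeR, 99 with introns left out, 43 with thinned reads, and 39 and 5 with Input control 3 and 4 or 1 and 2 left out. In control cells they were 16 with at least 20 reads, 3770 with no filter on PSI range, 44 by edgeR, 3 with only the 2 groups compared, 4 with introns left out, 5 with thinned reads, and 0 and 2 with Input control 3 and 4 or 1 and 2 left out. The size rule was met by 236 events in Input and 10 in polysomes with at least 20 reads, and by 37 in polysomes with at least 10 PSI points. With no filter on PSI range, events at a limit of PSI in every library were tested too. With 0.5 added to each read number, their log2 odds depend on the read number alone. Median reads per event were 36 to 40 in Input GEMIN5 and 54 to 76 in Input control. Calls without the filter can thus follow from read numbers, and cannot be read as numbers of changed splicing events. How many were at the limits was not counted. Beyond this, and except where fewer libraries, events or reads were used, the cause was not tested.

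Same-numbered samples did not deviate together (correlations −0.56 to 0.49), so the numbers were not taken as pairs. With a replicate block 6041, 35, 5098, 5563 and 8356 genes passed in Input, in polysomes, for the difference, in control and in GEMIN5 cells, 7, 7, 8, 11 and 11 lists, and 1150, 0, 19 and 0 events in Input, in polysomes, for the difference and in control, with 0 events shared by Input and polysomes. Not every sample correlated best with its own number. Under the block the difference between fractions passed for GEMIN5 (0.78, adjusted p = 0.00847), and the calls of CCNL1 (0.0612), TPGS2 (0.0832), ZNF330 (0.0739), UBAP2L (0.113) and ELOB (0.229), among others, were not made. The unfolded protein response list did not pass under it in Input (adjusted p = 0.0606) or in control (0.059), nor the uORF list for the difference (0.0528), while the interferon list passed in control (0.0463) and the immediate early list in GEMIN5 cells (0.0411).

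With each library left out in turn, genes ranged over 5427 to 6058 in Input, 9 to 90 in polysomes, 3912 to 5174 for the difference, 4534 to 5470 in control and 7585 to 8431 in GEMIN5 cells. Events ranged over 934 to 1063, 0 to 0, 75 to 267 and 4 to 11 in Input, in polysomes, for the difference and in control, and the size rule over 445 to 599 in Input and 37 to 49 in polysomes, where fewer libraries are easier to separate. Small event changes were rarely recovered. By limma a change of 10 PSI points was recovered in 1.49% of simulated events in Input and 0% in polysomes. At the same read numbers edgeR recovered 4.48% in each, so the choice of test also mattered.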

Other observations

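The tests of exon event reads, of the junctions of GEMIN5 and of transcript length were chosen after the results had been seen. Some genes with high counts had almost no reads in exon events. HFM1 held 1912 to 330765 counts per library, up to 2.57% of a library, but none of its 39 exon events had more than 5 corrected reads. SLCO5A1 held 320 to 59418 counts with at most 6 corrected reads in 9 events, and PDE3A 232 to 13635 counts with at most 3 in 20 events. TTC16, MATN1 and LAMA2 had at most 1, 2 and 3. Of 5068 genes with at least 5 exon events and a mean of 100 counts, 41 had no exon event with 10 reads in any library, and the median of the highest value was 93. What the counts of these genes measure was not tested.

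Spliced reads of GEMIN5 itself fell with distance from the 3′ end. In Input GEMIN5 the junction 962 nt away held a mean of 2006.3 reads and the one 5155 nt away 12.3, against 11.5 and 1.5 in Input control. In polysomes of GEMIN5 cells they held 1180.8 and 217.8, and in control 6.2 and 0.5.

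By transcript length, the median log2 change in Input, scaled to total counts only, was 0.29 for 377 genes of 500 to 1000 nt, −0.90 for 1647 of 1000 to 2000 nt and −1.44 for 1372 of 3000 to 4000 nt. It turned back to −1.28 for 1581 genes of 4000 to 6000 nt and −1.10 for 1098 of at least 6000 nt. Every bin in polysomes lay between −0.03 and 0.03. The first principal component of all libraries held 63.5% of the variance and the second 13.1%.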
